A study of Mus musculus with 12 samples.

How the data were processed

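The study sequenced 12 libraries, 3 in each of 4 groups, of MC3T3-E1 cells by a 3' mRNA-seq method. RNA was extracted with TRIzol, and the libraries were made with QuantSeq. The values used are counts per gene symbol and library as deposited, made per the submitters' processing notes with STAR 2.7.9a, featureCounts of Subread 2.0.3 and the mouse genome mm39. DESeq2 1.38.2 is also named there, without its role. The strand setting, annotation release and filters are not given in the sources used here, so antisense and overlapping genes cannot be told apart, and no gene positions are given. Reads of near-identical gene copies, such as Bglap and Bglap2 or the Orm genes, may be split between them, and their levels are uncertain.

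The table had 56691 genes, of which 20212 had 0 counts in all libraries. There were 882 entries with a repeated symbol, which were kept apart, and the entry with most counts kept the plain symbol. Genes were kept by edgeR's filterByExpr (min.count 10, min.total.count 15), which left 14394 genes with 99.4% of the counts. Library sizes were scaled by TMM. A quasi-likelihood model with robust dispersion was fitted to all 12 libraries with edgeR 4.0.16 in R 4.3.3, with 1 coefficient per group and no block. Genes were called at an adjusted p (Benjamini-Hochberg) under 0.05. Each SE is the absolute log2 fold change divided by the square root of the F statistic, and is approximate. CPM are TMM-scaled, given as mean ± SD over 3 libraries. The common biological coefficient of variation was 0.292.

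There were 3 main comparisons, 25(OH)D with control, 25(OH)D plus BGP with 25(OH)D, and 25(OH)D plus ZK191784 with 25(OH)D. The 2 combinations were also compared with control. The comparisons, 28 gene lists and the rule for naming genes were written before the data were examined. The rule named 12 core genes whatever their result. It added the 8 largest called rises and the 8 largest called falls with an average log2 CPM of at least 1, groups that did not overlap, and a symbol that was no Gm-number, clone or pseudogene name. It also added up to 4 called members with the smallest p from each list described. In the comparisons of the combinations with control it named core genes only. Of 481 list genes 367 were tested, and 26 lists had at least 5 of them. Lists were tested with camera in limma 3.58.1 (inter-gene correlation 0.01, prior count 3) and adjusted over the 26. Counts adjusted over the list alone are given beside.

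For 4 core genes too rare for the filter, and for called genes with few counts in the lower group, counts were summed by group. A gene with 0 counts in the lower group is given as its fold against an assumed 3 counts over that group. That fold leaves out the error of the higher count and is no confidence limit. A gene with 1 to 3 counts is given as a ratio with its 95% exact binomial interval. These intervals cover counting error only, and neither they nor the assumed 3 counts cover the spread between libraries. The exact permutation test used all splits of 3 against 3 libraries. The library ratio of ribosomal protein gene counts to pseudogene and Gm-numbered counts was chosen after the data had been seen. Opposite calls were set against 20 simulations from the fitted dispersions with equal group means, each gene drawn independently.

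The method was tested on simulated data. In negative binomial draws with planted changes it called 18, 11.2 and 24.2% of 2-fold and 69, 70 and 64.9% of 4-fold changes in the 3 main comparisons. It made 6, 5 and 6 wrong calls. These draws took each gene independently and so lack variation that many genes of a library share, and they do not show how many wrong calls such variation gives. Alternatives written beforehand were RLE normalization, DESeq2 1.42.0, no filter, a filter at a CPM of 2 in 3 libraries, a replicate block, the 2 groups alone, and leaving out each library. For lists an estimated correlation and fry were tried. Tried later, after seeing the data, were the library ratio as a covariate, RLE and leaving out libraries for the opposite calls, and synonyms for list symbols. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.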

Results

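MC3T3-E1 is a mouse calvarial pre-osteoblast line that differentiates and mineralizes its matrix in osteogenic medium. The cells were differentiated for 28 days in medium with 10 mM beta-glycerophosphate (BGP, a phosphate donor), 50 µg/ml ascorbic acid and 0.1 µM dexamethasone. From day 27 they received 25-hydroxyvitamin D (25(OH)D), the circulating precursor of the active vitamin D hormone, for 24 h. The dose was 100 µM as labelled, and its unit could not be checked from the sources used here and may be a slip. The 4 groups were an untreated control, 25(OH)D alone, 25(OH)D with a further 4 mM BGP, and 25(OH)D with 100 µM ZK191784. Each group had 3 libraries of 3' mRNA-seq. The deposited counts summed to between 3318723 and 5170980 per library. The totals were 4026050, 4762357 and 4431032 for control and 3978266, 4418903 and 3587039 for 25(OH)D. They were 3318723, 4970950 and 5170980 for 25(OH)D with BGP, and 5072719, 4161006 and 4382638 for 25(OH)D with ZK191784. The series title places FGF23, the phosphate-regulating hormone made by osteocytes, and the vitamin D metabolism of the cells at the centre of the study. The labels name no separate cultures for the replicates, so the p-values measure only the spread between these libraries.

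The libraries differed along an axis that the groups did not follow. One component held 60.3% of the variance within groups and the next held 7.3%. It ran with the balance between ribosomal protein gene counts and counts of their pseudogenes and of predicted Gm-numbered genes. The log2 ratio of these was −1.76, −1.87 and −0.68 in control, −0.55, −1.26 and −1.84 with 25(OH)D, −1.75, −0.55 and −1.22 with BGP, and −0.90, −1.23 and −1.67 with ZK191784. Its group means lay between −1.44 (control) and −1.17 (25(OH)D with BGP), with SDs from 0.39 to 0.66 (n = 3).

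**Figure D1:**
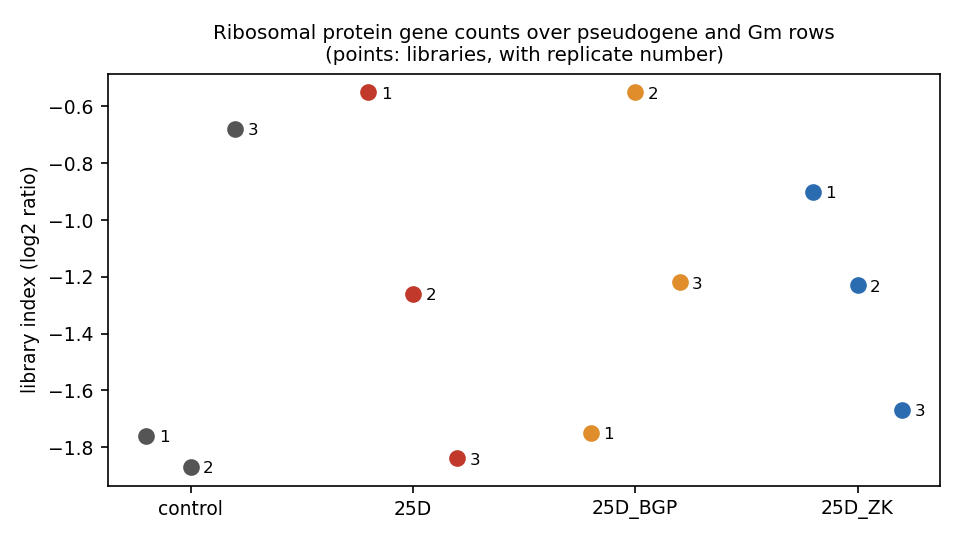
Log2 ratio of ribosomal protein gene counts to counts of their pseudogenes and Gm-numbered genes (vertical axis) in each of the 12 libraries, by treatment group (horizontal axis). Points are single libraries with their replicate number. Each group spans low and high values, from −1.87 in control library 2 to −0.55 in 25(OH)D library 1 and BGP library 2.

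The first comparison asked what 25(OH)D changed in the mineralizing cells. Spp1, which encodes the bone matrix protein osteopontin, rose 15.2-fold, from 3395 ± 401 to 51551 ± 5707 CPM (mean ± SD, n = 3 per group). Its log2 fold change was 3.93 ± 0.15 (SE), with adjusted p = 2.59e-08 by edgeR's quasi-likelihood test. Vdr, the gene of the vitamin D receptor, rose 6.54-fold, from 61.1 ± 9.91 to 399.6 ± 68.7 CPM (log2 2.71 ± 0.17, adjusted p = 9.34e-07). Enpp1, whose product generates pyrophosphate, a mineralization inhibitor, rose 4.54-fold, from 4.10 ± 1.20 to 18.6 ± 4.76 CPM (adjusted p = 0.000310). Phex, the gene mutated in X-linked hypophosphataemia, fell by 2.97 on the log2 scale (SE 0.48), from 19.4 ± 3.12 to 2.41 ± 1.90 CPM (adjusted p = 0.00143). Cyp24a1, the 24-hydroxylase that inactivates vitamin D metabolites and a classical target of the receptor, had 0 counts in the control libraries. It had 26, 12 and 2 counts in the 25(OH)D libraries, which was at least 14.7-fold higher against 3 counts over the group (adjusted p = 0.0200). The Cyp24a1 call was lost without control library 1 (adjusted p = 0.0540), control library 2 (0.0602) or 25(OH)D library 1 (0.0668), and with a replicate block. Galnt3, which glycosylates FGF23, had a log2 difference of −0.66 ± 0.42. Cyp27a1, a 25-hydroxylase, differed by 0.31 ± 0.53 and the osteocyte matrix gene Dmp1 by 0.29 ± 0.51, and none of these 3 passed the test (adjusted p = 0.456, 0.797 and 0.812).

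In all, 1250 of 14394 genes tested passed at an adjusted p under 0.05 (edgeR), 685 higher and 565 lower with 25(OH)D. At least 2-fold changes made up 489 of the higher and 382 of the lower genes. Leaving out 25(OH)D library 2 gave 813 genes, a fit on the 6 libraries of these 2 groups alone gave 763, and the library ratio as a covariate gave 2859.

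Among genes that met the naming rule the largest rise was that of Inmt. This gene of an indolethylamine N-methyltransferase had 0 counts in control and 10970 with 25(OH)D (938 ± 124 CPM, n = 3). This was 4034-fold higher against an assumed 3 counts over the control group. C3, the central complement component, rose from 0.971 ± 0.650 to 750.0 ± 138 CPM (log2 9.53 ± 0.49, adjusted p = 1.80e-07). Orm3, of the orosomucoid family of acute-phase proteins, rose by 8.21 ± 0.34 on the log2 scale. Reads of Orm3 could be split with its close paralogs, so its level is uncertain. Hsd11b2, whose product inactivates glucocorticoids, went from 0 to 122 counts, 44.9-fold higher against an assumed 3 counts. Lpl, the lipoprotein lipase, had 1 count in control and 164 with 25(OH)D, a ratio of 181 (95% counting interval 32.0 to 7188). Lrtm2 rose by 7.05 ± 0.61. Ccn2, a matricellular growth factor, was called at 7.29 ± 1.43 but varied widely between 25(OH)D libraries (76.4 ± 89.9 CPM), and its call was lost without the low-count filter (adjusted p = 0.0719).

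Among the same genes the largest fall was that of Ibsp, which encodes bone sialoprotein, a marker of mineralizing osteoblasts. It fell by 7.20 on the log2 scale (SE 0.44), from 13675 ± 5662 to 92.7 ± 35.5 CPM (n = 3, adjusted p = 6.18e-07). Has2, a hyaluronan synthase, fell by 5.29 (SE 0.44), from 28.0 ± 1.69 to 0.699 ± 0.558 CPM. Apln, which encodes the peptide apelin, fell by 5.25 (SE 0.53), and the serine protease gene Prss35 fell by 5.03 (SE 0.62). Adamts18, of the ADAMTS family of metalloproteases, had 114 counts in control and 2 with 25(OH)D, a ratio of 51.7 (13.98 to 432). Kctd14 had 109 against 2 counts (ratio 49.4, 13.4 to 413) and Myl10 had 152 against 3 (ratio 45.9, 15.4 to 225). Slc13a4, a sulfate transporter gene, had 75 against 2 (ratio 34.0, 9.09 to 286). These 4 had adjusted p = 0.000992, 0.000687, 0.000894 and 0.000489.

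**Figure D2:**
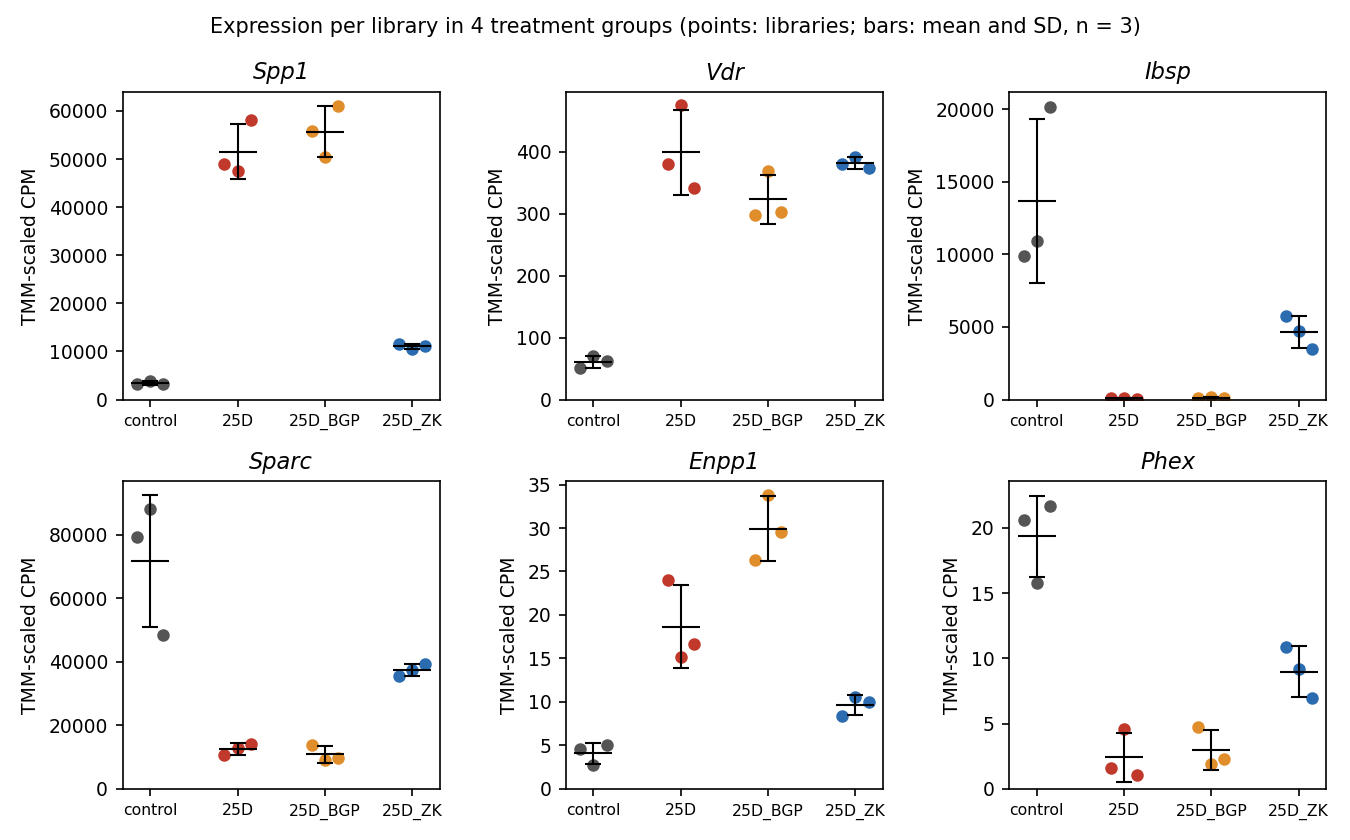
TMM-scaled CPM (vertical axes, linear) of Spp1, Vdr, Ibsp, Sparc, Enpp1 and Phex in each library of the 4 groups (horizontal axes). Points are libraries, and bars are the mean and SD (n = 3). Spp1 lies at 51551 ± 5707 CPM with 25(OH)D and 11082 ± 493 with added ZK191784, while Vdr lies at 399.6 ± 68.7 and 382 ± 9.65.

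The gene lists, fixed before the data were examined, were described by their called members and by camera, which compares a list with all other genes. Vitamin D response genes were higher with 25(OH)D. Of 18 measured, 7 rose and 1 fell, and 9 passed when adjusted over the list alone (camera adjusted p = 0.00113; adjusted p = 0.143 with an estimated correlation). The number that rose was 5 or 6 when any 1 library was left out. Besides Spp1, Vdr and Enpp1, the transcription factor gene Cebpb rose, by 1.77 ± 0.14. The 1 gene that fell was Tnfrsf11b, which encodes the osteoclast inhibitor osteoprotegerin (log2 −2.28 ± 0.46). Of 9 measured genes of vitamin D metabolism and receptors, 4 rose and 0 fell, with 4 adjusted over the list alone (camera adjusted p = 0.000148; adjusted p = 0.143 with an estimated correlation). Its members Fdxr and Por, which pass electrons to cytochrome P450 enzymes, rose by 2.17 ± 0.16 and 1.03 ± 0.14.

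Genes of osteoblast differentiation were lower with 25(OH)D. Of 21 measured, 14 fell and 2 rose, and 17 passed when adjusted over the list alone (camera adjusted p = 1.84e-10; adjusted p = 0.143 with an estimated correlation). Ifitm5, a bone-restricted membrane protein gene, fell by 4.75 on the log2 scale (SE 0.25). Sparc, which encodes osteonectin, fell by 2.52 (SE 0.24) and the type I collagen gene Col1a1 fell by 2.17 (SE 0.20). Runx2, the master transcription factor of the lineage, fell by 1.07 (SE 0.16), and was chosen after its value was seen. Alpl, the tissue-nonspecific alkaline phosphatase gene, was 1 of the 2 that rose (0.93 ± 0.21), a call lost without control library 2 (adjusted p = 0.0561), and was also chosen after its value was seen. The number that rose was 1 without control library 1 or 2 or 25(OH)D library 1 or 2. In the list of collagens and extracellular matrix 11 of 28 measured genes fell and 2 rose, with 16 adjusted over the list alone (camera adjusted p = 0.00113; adjusted p = 0.569 with an estimated correlation). Col11a1 and Thbs2 fell by 2.96 (SE 0.16) and 2.08 (SE 0.13), and Col3a1 fell by 2.12 (SE 0.22). The crosslinking enzyme gene Loxl2 and the fibrillin gene Fbn1 rose, by 3.03 ± 0.45 and 1.49 ± 0.30, and were chosen after their values were seen. Without 25(OH)D library 2 the number that fell was 7.

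Of the 14 measured osteocyte markers, 6 fell and 2 rose, with 10 adjusted over the list alone (camera adjusted p = 0.0395, lower; adjusted p = 0.143 with an estimated correlation). Besides Phex, the hyaluronan receptor gene Cd44 fell, by 1.02 (SE 0.18). Dstn, which encodes the actin-severing protein destrin, and Fam20c, the kinase of secreted phosphoproteins including FGF23, rose by 2.36 ± 0.19 and 1.26 ± 0.19. The camera call of this list was lost without control library 3 (adjusted p = 0.128) or 25(OH)D library 3 (0.0644). Among 17 measured genes of FGF23 regulation and processing, 3 rose and 2 fell, with 5 adjusted over the list alone, and camera made no call (adjusted p = 0.772). When any library other than control library 3 was left out 2 rose, and without 25(OH)D library 2 only 1 fell. Of 16 genes of mineralization and phosphate transport, 5 rose and 4 fell, with 9 adjusted over the list alone (adjusted p = 0.988). The number that rose was 2 without control library 2 and 3 without 25(OH)D library 1 or 2. Anxa2, an annexin of matrix vesicles, fell by 1.93 (SE 0.19). Of 8 genes of osteoclast regulation, 2 rose and 2 fell, with 4 adjusted over the list alone (adjusted p = 0.463), and the number that fell was 1 when any library other than control library 1 was left out. By fry this list was called, higher (adjusted p = 1.47e-05). The cytokine genes Il34 and Cxcl12 rose, by 3.97 ± 0.22 and 4.20 ± 0.31.

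Cell cycle genes were lower as a list, with 4 of 27 falling and 0 rising, and 7 adjusted over the list alone (camera adjusted p = 0.00101; adjusted p = 0.143 with an estimated correlation). The number that fell was 2 without control library 1 or 2 or 25(OH)D library 1 or 2. The replication gene Mcm5 fell by 1.14 (SE 0.19) and the mitotic gene Birc5 fell by 1.22 (SE 0.23). In cholesterol synthesis 4 of 23 genes rose and 6 fell, with 15 adjusted over the list alone, and the list was lower (camera adjusted p = 0.0395; adjusted p = 0.329 with an estimated correlation). Dhcr7, which turns 7-dehydrocholesterol into cholesterol, rose by 2.88 ± 0.18, as did Hsd17b7 by 1.86 ± 0.30. That list call was lost without control library 3 (adjusted p = 0.128) or 25(OH)D library 3 (0.172), and the number that fell was 2 without 25(OH)D library 2. The p53 and apoptosis list was higher, with 2 of 16 genes rising and 0 falling, 2 adjusted over the list alone (camera adjusted p = 0.0395; adjusted p = 0.336 with an estimated correlation). These were Sesn1 (3.11 ± 0.25) and Gdf15 (1.90 ± 0.28), and 4 rose without control library 3. Its camera call was lost without control library 1 (adjusted p = 0.0935), 25(OH)D library 1 (0.0851) or 25(OH)D library 2 (0.0625), and with the library ratio as a covariate (0.0530). The interferon response list was lower by camera with 0 of 20 genes called and 0 adjusted over the list alone (adjusted p = 0.0441; adjusted p = 0.835 with an estimated correlation). That call was lost without control library 1 (adjusted p = 0.341), control library 2 (0.143), 25(OH)D library 1 (0.189) or 25(OH)D library 2 (0.121). It was also lost by fry (0.334), with a replicate block and with the library ratio as a covariate (0.0599). In all 9 of 26 lists were called with the preset correlation and 0 with an estimated one. By fry 11 were called. These left out the interferon response and took in osteoclast regulation, oxidative stress (adjusted p = 0.00661, higher) and hypoxia and glycolysis (0.0127, lower).

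Fgf23 itself was too rare for the genome-wide test. It was counted 0, 1 and 0 times in the control libraries, 1, 3 and 3 times with 25(OH)D, 7, 4 and 7 times with added BGP, and 0, 1 and 1 times with added ZK191784. The ratio of 25(OH)D to control was 7.72 (95% counting interval 0.992 to 348, exact permutation p = 0.1, 2-sided). The ratio of 25(OH)D with BGP to 25(OH)D alone was 2.29 (0.912 to 6.48, exact permutation p = 0.2). Against control the combination with BGP gave a ratio of 17.7 (2.79 to 737, exact permutation p = 0.1). With ZK191784 the ratio to 25(OH)D alone was 0.251 (0.0255 to 1.32, exact permutation p = 0.1). With 3 against 3 libraries 0.1 is the smallest p that the exact test can give, and the intervals cover counting error only. Cyp27b1, the 1-alpha-hydroxylase that makes the active hormone, summed to 4, 6, 4 and 4 counts in the groups in the same order. Cyp2r1, the main 25-hydroxylase, summed to 23, 11, 13 and 17, and Tnfsf11, which encodes the osteoclast factor RANKL, to 0, 0, 7 and 2. The 7 counts of Tnfsf11 with BGP were 2, 0 and 5 per library, and the counting interval of their ratio to the 0 counts with 25(OH)D alone starts at 1.28 (exact permutation p = 0.4).

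The second comparison asked what a further 4 mM BGP changed in cells given 25(OH)D. Dmp1, the osteocyte matrix protein gene, had the smallest p among the core genes, at 10.2 ± 3.24 CPM with BGP and 3.07 ± 1.55 without (n = 3 each). Its log2 difference of 1.72 ± 0.47 did not pass the test over all genes (adjusted p = 1.000, edgeR, unadjusted p of 0.00313). Enpp1 stood at 29.9 ± 3.75 against 18.6 ± 4.76 CPM (0.68 ± 0.25, unadjusted p of 0.0189). Spp1 differed by 0.11 ± 0.13, Vdr by −0.31 ± 0.16, Phex by 0.26 ± 0.52, Cyp24a1 by −0.21 ± 0.80, Galnt3 by 0.53 ± 0.43 and Cyp27a1 by 0.01 ± 0.52. All 8 measured core genes had the same adjusted p = 1.000.

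With edgeR 0 of 14394 genes passed, with 268 at an unadjusted p under 0.05 where 720 would be expected by chance, and DESeq2 also called 0. With the library ratio as a covariate 6 genes passed. Planted changes made by thinning these counts were called in 54% of cases at 4-fold and in 19% at 2-fold, so most 2-fold changes would be missed. Of the 26 lists 0 were called, with 6 at an unadjusted p under 0.05, 0 with an estimated correlation and 0 by fry, against 3 with the library ratio as a covariate and 2 with synonyms for list symbols. Cholesterol synthesis, FGF23 regulation and the interferon response, higher with BGP, and collagens and extracellular matrix, lower, each had adjusted p = 0.0799. Of 11 alternatives, 2 called FGF23 regulation (lowest camera adjusted p = 0.0408) and 4 cholesterol synthesis. The interferon response was called in 3 of them, as were collagens and extracellular matrix. Among osteocyte markers 1 of 14 passed when adjusted over the list alone, which was Dmp1 (0.0438). Dmp1 did not pass over the FGF23 regulation list alone (0.0532) or that of mineralization (0.0501). The list count was 1 without 25(OH)D library 1 or 2, 2 without 25(OH)D library 3 or BGP library 1, 3 without BGP library 2 and 0 without BGP library 3.

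The third comparison asked what ZK191784 changed in cells given 25(OH)D. The labels give ZK191784 by its code name, and no group received it alone. Spp1 fell by 2.22 on the log2 scale (SE 0.14), from 51551 ± 5707 to 11082 ± 493 CPM (n = 3 each, edgeR adjusted p = 4.00e-06). Ibsp rose 50.2-fold, from 92.7 ± 35.5 to 4654 ± 1131 CPM (5.65 ± 0.41, adjusted p = 9.35e-06). C3 fell by 6.94 (SE 0.41), from 750.0 ± 138 to 6.13 ± 3.03 CPM. Vdr stood at 382 ± 9.65 against 399.6 ± 68.7 CPM, a log2 difference of −0.06 ± 0.16 (adjusted p = 0.972). Phex (1.87 ± 0.48) and Enpp1 (−0.95 ± 0.26) did not pass (adjusted p = 0.0567 and 0.0815). Cyp24a1 had 3 counts against 40, a ratio of 0.0660 (95% counting interval 0.0131 to 0.207), and did not pass (adjusted p = 0.112). DESeq2 called all of Phex, Enpp1 and Cyp24a1 (adjusted p = 0.00602, 0.0314 and 0.0388), as did the fit with the library ratio as a covariate (0.000688, 0.00421 and 0.00471). Over all alternatives the adjusted p ran from 0.000688 to 0.215 for Phex, from 0.00421 to 0.341 for Enpp1 and from 0.00397 to 0.420 for Cyp24a1. Without 25(OH)D library 2 Phex passed (adjusted p = 0.0134), and without 25(OH)D library 3 Cyp24a1 passed (0.0379). Galnt3, Dmp1 and Cyp27a1 differed by 0.55 ± 0.42, 0.26 ± 0.49 and −0.23 ± 0.52 and did not pass.

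Other large rises with ZK191784 were those of Col2a1, the type II collagen gene (4.02 ± 0.55), Prss35 (3.59 ± 0.62), Ifitm5 (3.53 ± 0.24) and Car3, a carbonic anhydrase gene (3.51 ± 0.19). Kctd14 had 55 against 2 counts (ratio 24.2, 6.39 to 205) and Slc13a4 41 against 2 (ratio 18, 4.69 to 154). Stox2 had 43 against 3 counts (ratio 12.6, 4.04 to 63.6). Its call (adjusted p = 0.0434) was lost without 25(OH)D library 1, 2 or 3 (0.144, 0.0995 and 0.128) or ZK191784 library 1 or 2 (0.116 and 0.168), and with a replicate block. Lrtm2 had 2 counts against 520, a ratio of 25(OH)D alone to the combination of 295 (81.4 to 2446). Hsd11b2 had 1 against 122 (ratio 139, 24.4 to 5519) and the chemokine-like receptor gene Cmklr1 3 against 54 (ratio 20.5, 6.64 to 102). Gprc5a, an orphan receptor gene, fell by 4.90 (SE 0.25), Ccrl2, an atypical chemerin receptor gene, fell by 4.51 (SE 0.58) and the keratin gene Krt17 fell by 4.27 (SE 0.59). Hgd, of tyrosine breakdown, had 2 against 55 counts (ratio 31.2, 8.25 to 264). Its call (adjusted p = 0.0160) was lost without 25(OH)D library 1 or 2 (0.0549 and 0.0744) or ZK191784 library 1 or 2 (0.0798 and 0.0881), and with a replicate block.

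Osteoblast differentiation genes were higher with ZK191784. Of 21 measured, 10 rose and 0 fell, with 16 adjusted over the list alone (camera adjusted p = 6.95e-11; adjusted p = 0.145 with an estimated correlation). The number that rose was 6 without 25(OH)D library 2 or ZK191784 library 1. Besides Ibsp and Ifitm5, Col1a1 rose by 1.44 ± 0.20, Dlx5, a homeobox factor of the lineage, by 1.62 ± 0.23, Sparc by 1.58 ± 0.23 and Runx2 by 0.93 ± 0.16, the last 2 chosen after their values were seen. Of 28 genes of collagens and extracellular matrix 5 rose and 0 fell, with 13 adjusted over the list alone (camera adjusted p = 0.000233; adjusted p = 0.595 with an estimated correlation). By fry that list was not called (adjusted p = 0.0952). Col11a1, Thbs2 and Col3a1 rose by 1.68 ± 0.15, 1.27 ± 0.13 and 1.52 ± 0.22. Of 18 vitamin D response genes 1 rose and 4 fell, with 8 adjusted over the list alone (camera adjusted p = 0.0115, lower; adjusted p = 0.220 with an estimated correlation). With any 1 of the 6 libraries left out 0 of these rose, and 2 fell without 25(OH)D library 2 or ZK191784 library 2 or 3. Cebpb fell by 1.10 (SE 0.13). Of 9 genes of vitamin D metabolism and receptors 2 fell and 0 rose, with 3 adjusted over the list alone (camera adjusted p = 0.0326; adjusted p = 0.595 with an estimated correlation). The number that fell was 0 without 25(OH)D library 1 or 2 or ZK191784 library 1, 2 or 3. That camera call was lost without 25(OH)D library 1 (0.0705) or 2 (0.154) or ZK191784 library 1 (0.0702) or 3 (0.0846). Fry made no call of this list (adjusted p = 0.0952).

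As a list, osteocyte markers were higher by camera (adjusted p = 0.0225; adjusted p = 0.208 with an estimated correlation), with 2 of 14 rising, 3 falling and 10 adjusted over the list alone. The number that rose was 0 without 25(OH)D library 1 or 3 or ZK191784 library 1 or 2, and 1 without 25(OH)D library 2 or ZK191784 library 3. The number that fell was 1 without 25(OH)D library 2 or 3 or ZK191784 library 1 or 2. Dstn fell by 1.21 (SE 0.18). This list call was lost without 25(OH)D library 3 (adjusted p = 0.0583). Genes of the cell cycle were higher as a list with 0 of 27 called and 2 adjusted over the list alone (camera adjusted p = 0.0225; adjusted p = 0.529 with an estimated correlation). Their call was lost without 25(OH)D library 2 (0.0946) or 3 (0.0808) or ZK191784 library 1 (0.344), and by fry (0.0952). Without 25(OH)D library 3, 1 gene rose. Genes of the interferon response were higher with 0 of 20 called and 0 adjusted over the list alone (camera adjusted p = 0.0426; adjusted p = 0.872 with an estimated correlation). Leaving out 25(OH)D library 1 (0.249) or 2 (0.154) or ZK191784 library 2 (0.0578) or 3 (0.546) ended it, as did fry (0.513) and a replicate block. Outside the called lists, Il34 and Cxcl12 fell by 2.01 (SE 0.20) and 2.48 (SE 0.29). Dhcr7 fell by 2.08 (SE 0.17), and the fatty acid desaturase gene Scd1 fell by 1.69 (SE 0.14).

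In this comparison 508 genes passed (edgeR), 205 higher and 303 lower with ZK191784, of which 146 and 206 changed at least 2-fold. The count was 328 without 25(OH)D library 1, 283 without 25(OH)D library 2, and 302, 269 and 319 without ZK191784 library 1, 2 and 3, and 1616 with the library ratio as a covariate. Of the 26 lists 7 were called with the preset correlation, 0 with an estimated one and 4 by fry. Fry lost 4 of the 7 and gained osteoclast regulation (lower, adjusted p = 0.00358).

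Whether ZK191784 gave a reversal of the 25(OH)D changes was asked next. Of the 1250 genes called with 25(OH)D, 483 were called the opposite way when ZK191784 was added and 1 the same way. Among them 291 rose and then fell, as did Spp1 and C3, and 192 fell and then rose, as did Ibsp and Sparc. Both comparisons use the 25(OH)D libraries, which alone can tie them. Independent lists of these sizes would give 22.5 opposite and 21.6 same-way calls. In 20 simulations with equal group means there were 0 opposite calls, which is chance with no effect and does not show what the shared libraries give among called genes. The covariance of the log2 fold changes was −0.412 against −0.106 in the simulations, a difference of −0.306. The simulations drew genes independently, without the axis shared between libraries, so they do not show what that axis adds. Part of the excess over independent lists can come from the shared libraries. Against the 25(OH)D libraries with BGP in their place, 468 genes differed from the ZK191784 group, and 411 of these were opposite to 25(OH)D against control. The number of 483 was 316 without 25(OH)D library 1, 274 without 25(OH)D library 2, and 295, 262 and 312 without ZK191784 library 1, 2 and 3. With the library ratio as a covariate it was 1383, among 2859 genes called with 25(OH)D and 1616 with ZK191784. For BGP the opposite calls with edgeR were 0 because the comparison itself called 0 (268 genes at an unadjusted p under 0.05, and 0 by DESeq2), and the covariance was −0.101 against −0.105 in the simulations.

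**Figure D3:**
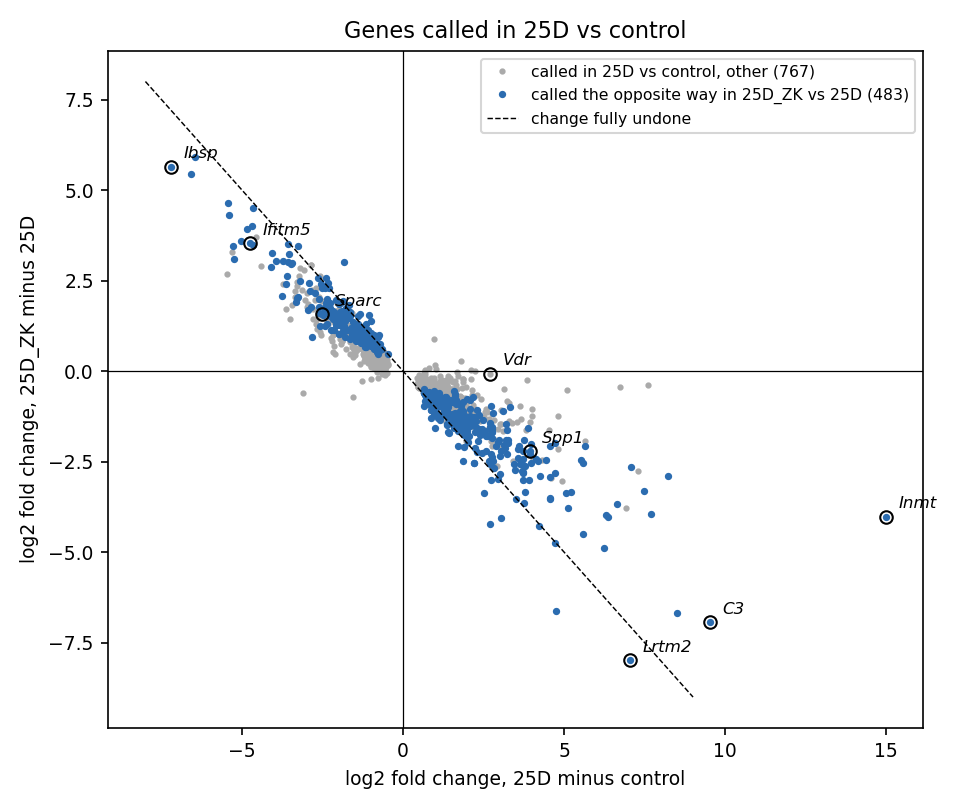
Log2 fold change of 25(OH)D with ZK191784 minus 25(OH)D alone (vertical axis) against 25(OH)D minus control (horizontal axis) for the 1250 genes called in the latter. Blue points are the 483 genes called the opposite way, grey points the other called genes, and the dashed line marks a change fully undone. Ibsp lies at the upper left, Spp1 and C3 lie at the lower right, and Vdr lies near 0 on the vertical axis. The horizontal value of Inmt rests on 0 counts in control and is set by the prior count.

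The 2 combinations were also compared with control. For 25(OH)D with BGP, 1187 genes passed (edgeR), 561 higher and 626 lower, against 712 in a fit on these 2 groups alone and 2671 with the library ratio as a covariate. Spp1, Vdr and Enpp1 rose by 4.04 ± 0.15, 2.40 ± 0.17 and 2.87 ± 0.28 on the log2 scale, and Phex fell by 2.71 (SE 0.46, n = 3 per group). Dmp1 rose from 2.52 ± 1.43 to 10.2 ± 3.24 CPM (2.01 ± 0.48, adjusted p = 0.0187). The Dmp1 call was lost without control library 1 or 2 (adjusted p = 0.0729 and 0.0796) or BGP library 2 or 3 (0.0754 and 0.0566). It was also lost with the 6 libraries of the 2 groups alone (0.0567) and with a replicate block. Cyp24a1 had 41 counts against 0, 13.4-fold higher against an assumed 3 counts over the control group (adjusted p = 0.0255), with a counting interval from 10.4. Its call was lost without control library 1 or 2 (0.0645 and 0.0726) or BGP library 2 or 3 (0.0744 and 0.0590), and with a replicate block. Galnt3 and Cyp27a1 differed by −0.13 ± 0.41 and 0.33 ± 0.52 and did not pass.

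For 25(OH)D with ZK191784 against control, 104 genes passed (edgeR), 73 higher and 31 lower, and DESeq2 called 224. Vdr rose by 2.64 ± 0.17 (adjusted p = 1.08e-05) and Spp1 by 1.71 ± 0.14 (adjusted p = 6.93e-05). Enpp1 (1.24 ± 0.29) and Phex (−1.10 ± 0.42) did not pass (adjusted p = 0.0928 and 0.536). Over the alternatives Enpp1 ran from 0.00386 to 0.364 and passed with DESeq2, without the filter and with the library ratio as a covariate, and Phex ran from 0.0206, with that covariate, to 1.000. Galnt3, Dmp1 and Cyp27a1 differed by −0.11 ± 0.41, 0.54 ± 0.50 and 0.08 ± 0.53. Cyp24a1 had 3 counts against 0, both at or under the floor of 3 counts over the group. Without control library 1 or 2 the count of called genes was 40 or 47, without ZK191784 library 1, 2 or 3 it was 48, 34 or 62, without the low-count filter it was 220, on the 2 groups alone 42, and with the library ratio as a covariate 676. The difference between this count and the 1250 genes of 25(OH)D alone was not itself tested.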

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

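Using the library ratio as a covariate, or RLE or leave-one-out for the opposite calls, or synonyms for list symbols, was chosen after seeing the data. The cause of each change below was not tested, except that leaving out libraries or groups leaves fewer samples.

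With the covariate the called genes became 2859 for 25(OH)D against control, 6 for added BGP, 1616 for added ZK191784, and 2671 and 676 for the combinations with BGP and ZK191784 against control. All 1250 and 508 genes called without it were kept. The opposite calls (reversal) became 1383 for ZK191784 and 5 for BGP, and 3 lists were called for BGP, against 0 without it. Synonyms for 2 list symbols gave 2 lists for BGP. The 2 groups alone gave 763 genes for 25(OH)D, 712 for 25(OH)D with BGP against control and 42 for 25(OH)D with ZK191784 against control. For the latter DESeq2 gave 224 and no filter 220, where 104 were called. DESeq2 gave 1466 for 25(OH)D and 700 for ZK191784. An estimated correlation left 0 lists for 25(OH)D and 0 for ZK191784, and fry gave 11 and 4.

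Leaving out single libraries gave 813 to 1266 genes for 25(OH)D, 269 to 428 for ZK191784, and 34 to 119 for its combination against control. The lowest values came without 25(OH)D library 2, ZK191784 library 2 and ZK191784 library 2. Called lists ranged from 0 to 3 for BGP and from 4 to 6 for ZK191784, and the opposite calls of the reversal from 262 to 510. No called result changed direction in any setting, while uncalled values near 0, such as those of Cyp27a1 and Dmp1 with 25(OH)D, took either sign. Of 201 named gene results, those of 25(OH)D against control changed label by leave-one-out in 98 of the tests run and kept it in 544, and those of ZK191784 against 25(OH)D lost the call in 125, gained it in 2 and kept their label in 293.

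No pairing by replicate number was seen. Of 18 same-number pairs 4 had a correlation over 0.1 (−0.72 to 0.63), and 3 of 12 libraries correlated best with their own number. The correlations were taken with the library axis left in, so a weaker pairing could not be excluded. With a replicate block 953 genes were called for 25(OH)D, 0 for BGP, 334 for ZK191784, and 900 and 56 for the combinations against control. It gave 324 opposite calls, and 8 and 6 lists for 25(OH)D and ZK191784. Depth limits the rare core genes, such as Fgf23 with 1 to 18 counts per group.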

Other observations

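The tests of the BGP result and of a shared share for ZK191784 were chosen after the results had been seen.

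The lists below were fixed beforehand and camera called none of them in either treatment comparison. With 25(OH)D, Scd1 (1.94 ± 0.14) and Aacs (1.37 ± 0.24) rose in fatty acid synthesis, where 2 of 15 genes rose, 1 fell and 4 passed when adjusted over the list alone (adjusted p = 0.572). With ZK191784 added, 2 of the 15 fell and 2 passed over the list alone (adjusted p = 0.975). In Wnt signalling 3 of 15 rose and 2 fell, with 6 over the list alone (adjusted p = 0.894). The agonist gene Rspo3 rose by 3.25 ± 0.48 and Ccn4 fell by 2.15 (SE 0.33). With ZK191784 1 rose and 1 fell, with 3 over the list alone (adjusted p = 0.542). In FGF and ERK feedback 3 of 19 rose and 0 fell, with 4 over the list alone (adjusted p = 0.782), namely Phlda1 (3.88 ± 0.43), the phosphatase gene Dusp5 (1.64 ± 0.19) and Egr1 (0.81 ± 0.15). With ZK191784 3 fell and 1 rose, with 4 over the list alone (adjusted p = 0.673), and the riser was Ier3 (1.27 ± 0.12). In the oxidative stress (NRF2) list 2 of 16 rose, with 3 over the list alone (adjusted p = 0.150). Pgd, of the pentose phosphate pathway, rose by 2.57 ± 0.18 and fell by 2.20 (SE 0.17) with ZK191784, when 2 fell, with 3 over the list alone (adjusted p = 0.542). In hypoxia and glycolysis 1 of 18 rose and 1 fell, with 2 over the list alone (adjusted p = 0.439), and Ldha fell by 1.16 (SE 0.13). With ZK191784 0 were called and 0 over the list alone (adjusted p = 0.975). In the unfolded protein and integrated stress response 2 of 21 rose and 1 fell, with 4 over the list alone (adjusted p = 0.894), and Psat1, of serine synthesis, fell by 1.80 (SE 0.18). The median of this list was negative and its mean positive, as in osteoclast regulation, Wnt signalling, FGF and ERK feedback, inflammation and NF-kB, LXR target genes, the glucocorticoid response and adipocyte markers.

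Called members in the remaining lists were few. C3 was the 1 called gene of 15 in inflammation and NF-kB (2 over the list alone, adjusted p = 0.752) and Lpl the 1 of 10 LXR target genes (1 over the list alone, adjusted p = 0.726). Of 6 adipocyte markers 1 rose and 1 fell (2 over the list alone, adjusted p = 0.894), and of 6 muscle markers 1 rose (2 over the list alone, adjusted p = 0.625). Of 11 genes of the glucocorticoid response 0 were called and 3 passed over the list alone (adjusted p = 0.894). Of 9 mitochondrially encoded transcripts 1 rose (2 over the list alone, adjusted p = 0.439), and of 7 fibroblast and progenitor markers S100a4 fell, by 2.26 (SE 0.16; 1 over the list alone, adjusted p = 0.439). With ZK191784 that fibroblast and progenitor markers list had adjusted p = 0.102, and was called without 25(OH)D library 1 (0.0496) or ZK191784 library 3 (0.0415) and with the library ratio as a covariate (0.0293). Of 9 macrophage and haematopoietic markers 0 were called (0 over the list alone, adjusted p = 0.782), as were 0 of 4 endothelial markers. Of 3 measured chondrocyte markers the matrix genes Col2a1 and Hapln1 fell, by 4.68 (SE 0.55) and 2.88 (SE 0.44), and both rose with ZK191784. The latter Hapln1 call was lost without 25(OH)D library 2 (adjusted p = 0.0657) or ZK191784 library 1 (0.0518).

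The counts of these small lists moved when single libraries were left out. With 25(OH)D the genes rising ran from 1 to 4 in Wnt signalling, 1 to 3 in inflammation and NF-kB, 1 to 2 in the stress response list, 0 to 2 in the glucocorticoid response, 0 to 2 among mitochondrially encoded transcripts, 0 to 1 among muscle markers and 0 to 1 among fibroblast and progenitor markers. Those falling ran from 0 to 2 in fatty acid synthesis, 1 to 2 in hypoxia and glycolysis, and 0 to 1 among adipocyte markers and in the FGF and ERK feedback, glucocorticoid and NRF2 lists. With ZK191784 the 3 falling in FGF and ERK feedback (Phlda1, Dusp5 and Egr1) became 0 without 25(OH)D library 1 or 2 or ZK191784 library 1, 2 or 3. In Wnt signalling 0 to 1 rose and 0 to 1 fell, in the NRF2 list 1 to 2 fell, and of the chondrocyte markers 1 to 2 rose.

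The following genes lie outside the naming rule and were chosen after their values were seen. They were not followed singly through the alternatives. With the library ratio as a covariate all genes called for 25(OH)D and for added ZK191784 kept their calls. Igfbp5, which encodes an IGF-binding protein, rose from 23.4 ± 13.6 to 2332 ± 740 CPM with 25(OH)D (log2 6.64 ± 0.50, n = 3, adjusted p = 4.04e-06) and fell by 3.66 (SE 0.44) with ZK191784. Gadd45a, a growth arrest gene, rose by 5.63 ± 0.53 and fell by 2.08 (SE 0.44). Tgm2, a transglutaminase gene, rose by 5.53 ± 0.23 and fell by 2.47 (SE 0.19). Hp, which encodes the acute-phase protein haptoglobin, rose from 335 ± 92.8 to 3095 ± 500 CPM (3.21 ± 0.20) and fell by 1.62 (SE 0.19). Itpr2, an inositol trisphosphate receptor gene, rose from 96.1 ± 3.61 to 1059 ± 45.8 CPM and stood at 160.1 ± 4.76 CPM with ZK191784.

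One axis held 60.3% of the variance within groups. Its loading on genes had a Spearman rho of 0.12 with transcript length and −0.12 with GC share across tested genes (−0.10 and −0.17 in protein-coding genes). The median longest transcript was 2416 bases in the 5% of genes highest on the axis and 1412 in the 5% lowest. These medians take all gene types together, and the sign for length turned in protein-coding genes. A part for length or GC was left open. Without pseudogenes, Gm-numbered genes and genes with a pseudogene of their own name the axis held 60.4%, so these genes alone did not make it. Genes copied only by Gm-numbered pseudogenes stayed in, so the test could not exclude reads shared between copies. Median loadings of the lists ran from percentile 12 (interferon response) to 88 (fibroblast and progenitor markers), with osteoblast differentiation at 73.8. The source is not known, and these values do not separate RNA or library preparation from the state of the cells. Of the tested genes 7373 followed the library ratio.

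With added BGP 0 genes were called. With the library ratio as a covariate 6 were, C3 (log2 −0.79 ± 0.13), Cxcl12 (−0.63 ± 0.11), Prkg2 (1.03 ± 0.17), Cnp (−0.59 ± 0.11), Slc43a2 (−0.56 ± 0.11) and Ramp1 (0.81 ± 0.16), and the other splits of the same libraries gave at most 0. With thinned counts 19% of planted 2-fold changes were called, so low power may also have hidden changes. Variance along the library axis and low power both fit and were not told apart, since the thinned counts kept that variance. Neither shows that more changes were there, so little change from the further BGP was left open as well.

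Over the 1250 genes called with 25(OH)D, ZK191784 undid a median share of 0.64 of the log2 change. With the 25(OH)D plus BGP libraries in place of the shared ones it was 0.56 (bootstrap over genes 0.54 to 0.58). That interval leaves out the spread between libraries. The shared libraries alone may thus not account for the opposite changes. Tested in the 25(OH)D libraries, 3.1% of the genes differed from 0.56 (14 less and 25 more undone), but that share lies under their own median of 0.64. This may account for some of the 25 but cannot give the 14. Among the 14, Inmt and Gm30624 had 0 counts in control, so their 25(OH)D change is set by the prior count and their shares are uncertain. With the BGP libraries the median share was 0.51 in genes that rose with 25(OH)D and 0.63 in genes that fell. Of the 14 genes 12 had risen, and of the 25 genes 17. Among the core genes called with 25(OH)D 1 differed, Vdr, on the less undone side, with a share of 0.02 (adjusted p = 9.21e-05), against 0.57 for Spp1, so one common share did not hold at Vdr. Without a ZK191784 group of its own, an effect of ZK191784 apart from 25(OH)D could not be separated.

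Each set of 6 libraries has 10 splits of 3 against 3, too few for a share under 0.05. For 25(OH)D against control 2 of the 10 splits had as many called genes, the real one with 1250 and another with 1857. The latter put control libraries 1 and 2 with 25(OH)D library 3, the 3 with the lowest library ratios. With that ratio as a covariate it gave 0 and the real split 2859. The ratio nearly follows this other split, so its 0 was close to fixed beforehand and does not favour the real split. For lists 1 split had as many, the real one with 9, and the highest other had 4. For added BGP all 10 splits had as many genes as the real one (0, highest other 0), and 10 as many lists (0, highest other 4). For added ZK191784 1 split had as many genes (508, highest other 0) and 1 as many lists (7, highest other 6). Against control 1 split had as many genes for 25(OH)D with BGP (1187, highest other 0) and 1 for 25(OH)D with ZK191784 (104, highest other 0).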
